A study of Homo sapiens with 14 samples.

How the data were processed

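RNA of HEK293T cells, wild type and SETD2 knockout, was extracted with a column kit, depleted of ribosomal RNA and sequenced, per the labels' protocols, with 3 libraries listed for each genotype. The label of a wild type library carries a ChIP protocol in place of an RNA protocol. Nothing in the labels says whether the libraries of a group came from separate cultures, so the deposited p-values measure only the spread between these libraries, which may be technical. The submitters' processing notes name TopHat, Cuffdiff and Bowtie 1.1.2 and the human genome build hg19, without role or order. The annotation is not given in the sources used here. The 8 ChIP samples were not analysed here.

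The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the total of mapped fragments) as 1 value per transcript and group, with lower and upper bounds of each value in the tracking table, whose level is not given in the file. The authors also deposited a table of tests with the FPKM values of both groups, the log2 fold of wild type over knockout, a test statistic, which is a score with no fixed range, and a p-value and q-value per transcript, per the file headers. The sign of the log2 fold was turned so that positive means higher in the knockout. It differed from the fold recomputed from the group values by at most 5.43e-05. Deposited p-values came in steps of 5e-05, and the called transcripts held 2 values of p, 195 of them at 5e-05 (q = 0.0220) and 24 at 0.0001 (q = 0.0392) in the authors' deposited table. The table named for genes and the table named for transcripts were identical, and in both each of the 204092 rows was an Ensembl transcript that served as its own gene. Results for genes and for transcripts are therefore the same, and sums over transcripts of a locus were used where a value per gene was needed. FPKM were summed per locus after loci with a failed estimate, those with the status HIDATA (24 transcripts) or FAIL (26 transcripts), were left out. A further 118190 transcripts had not been tested.

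The files pair no transcript with a gene name, and 0 of the 204092 IDs matched either table of gene names used here. No gene is named for this reason, the levels of SETD2 and PLK1 were not analysed here, and the knockout was not checked at the RNA level. The 35 gene lists fixed before the data were examined were not tested either. Positions are those of the authors' files on hg19, with 1 added to each start because the files count from 0.

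Group values permit no test between libraries, so the authors' q-value at 0.05 was used as it stood. The groups, the tests of calls, 10 of the 21 alternatives and the rule for named items were chosen before the data were examined. The rule took the 10 largest rises and the 10 largest falls by log2((knockout FPKM + 1)/(wild type FPKM + 1)) among called transcripts of at least 1 FPKM in a group. Its condition on gene symbols could not be applied, and items are named by position. Folds in the text are ratios of FPKM without a pseudocount, and none is given against a value of 0.

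Called transcripts were counted per chromosome (1 to 22 and X) and tested with a two-sided Fisher exact test against the other tested transcripts, with Benjamini-Hochberg adjustment over 46 pairs of chromosome and direction. Log2 folds of locus sums were taken over loci of at least 1 FPKM in a group and above 0 in both. The bounds of 1.2-fold and 1.5-fold for sums at called loci were chosen after the data were seen. The median fold of each chromosome was placed among 10000 random sets of the same size drawn within 20 bins of mean expression, a comparison planned for gene lists and applied to chromosomes after the data were seen. The scan for a step, chosen after the data were seen, took log2 folds held within ±1, left at least 10 loci on each side, and compared the best step with 9999 random orders of the loci of that chromosome. Neighbouring loci are not independent, so its p-values are too small where genes of a cluster change together. On folds shuffled over the 12424 loci, with a log2 shift of 0.3 put on 2 chromosomes, 1 whole and 1 in part, the set comparison found both and called 0 others, and the scan found the 1 step put in and called 0 others. Shuffled folds hold no trend with locus density or position, so this cannot show what the scan calls where such a trend exists. For the closing section, a knockout library present in 1 table only was computed, after the data were seen, as 3 times the tracking value divided by 0.978, minus 2 times the test-table value, where 0.978 is 1.5 times the most frequent ratio of the tables. On 204092 simulated transcripts this returned the simulated library to within 0.0024% of the group value. The simulated values were built with the same formula, so this checks the arithmetic and rounding only. It cannot show whether the deposited tables differ by a library. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

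Alternatives covered the q threshold, a minimum change, minima of 1 and 5 FPKM, the set of transcripts adjusted over, centring of the folds, and, added after the data were seen, 11 that used the tracking table, the deposited intervals, values above 0 in both groups, transcripts against loci, loci with a single transcript, and for chromosome 3 a minimum of 5 FPKM and centring. Where FPKM are scaled to the total of each library, a change in very abundant short or mitochondrial RNA moves all other values. How the authors scaled the libraries to each other is not given in the sources used here. An exact 0 in such a table can be a failed estimate. A transcript's share of its locus rests on how reads were assigned among overlapping transcripts, and overlapping genes on opposite strands share a locus.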

Results

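The series compared HEK293T cells, a line of human embryonic kidney cells that carries the SV40 large T antigen, with HEK293T cells in which SETD2 had been knocked out. SETD2 is the methyltransferase that places the trimethyl mark on lysine 36 of histone H3 along transcribed genes, and the series title names the mitotic kinase PLK1 as a candidate target in clear cell renal cell carcinoma that lacks SETD2. The labels list 14 samples. The 6 RNA libraries, 3 of wild type and 3 of knockout cells, were made from RNA depleted of ribosomal RNA. The 8 ChIP samples against H3K36me3 and H4K16ac, 2 for each mark and genotype, were not analysed here.

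The RNA values were group values of 204092 transcripts at 35671 loci, with no value for a single library and no read counts, so the depth of each library is unknown and no spread between libraries could be computed. Errors given below are the intervals the authors deposited with the tracking-table values, which for the knockout differ from the test-table values. The FPKM values of the knockout summed to 1273410 and those of the wild type to 1353660. Short transcripts and mitochondrial transcripts held much of both sums: loci of at most 300 bases took 21.5% in the knockout and 28.2% in the wild type, and the mitochondrial chromosome took 26.6% and 29.5%. At least 1 FPKM was listed for 51976 transcripts in the knockout and for 51106 in the wild type. A value above 0 was listed for fewer transcripts in the knockout, 97059 against 119701 in the test table and 103775 against 119895 in the tracking table.

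Each group appeared in both deposited tables, the FPKM tracking table and the table of tests. For the wild type the tracking value was a nearly fixed multiple of the test-table value, with a median ratio of 0.976 and a range of 0.974 to 0.979 between the 5th and 95th percentiles of 64400 transcripts of at least 0.5 FPKM. For the knockout the ratio ran from 0.652 to 1.65 between the same percentiles of 63811 transcripts. In the knockout 18022 transcripts lay within 1% of a ratio of 0.652 and 8 lay more than 2% below it. A knockout value of 0 in the test table stood beside at least 1 FPKM in the tracking table for 1051 transcripts, which occurred for 0 transcripts in the wild type. The labels list 3 knockout libraries, but how many entered each column is not given in the sources used here. Folds below use the test table unless the tracking table is named.

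**Figure D1:**
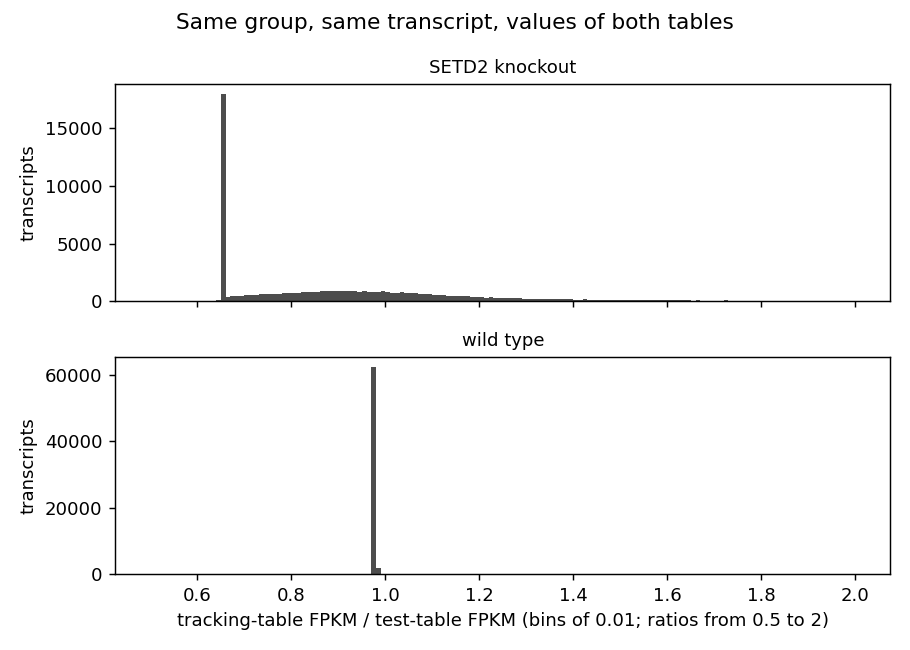
Histograms of the tracking-table FPKM divided by the test-table FPKM of the same group and transcript, for transcripts of at least 0.5 FPKM in the test table (vertical axis, number of transcripts; horizontal axis, ratio in bins of 0.01). The wild type ratios (lower panel) stand at 0.976, whereas the knockout ratios (upper panel) spread upward from a sharp peak at 0.652.

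The comparison of knockout with wild type RNA addressed which transcripts change when SETD2 is lost. Of 85852 tested transcripts in the authors' deposited table, 219 passed a q-value of 0.05, and they lay at 213 loci. Of these, 54 rose and 165 fell in the knockout, so that 24.7% of the called transcripts were higher. Among the 154 called transcripts with a value above 0 in both groups, 35 rose by a median of 2.79-fold and 119 fell by a median of 3.09-fold. The smallest change among them was 1.70-fold. The other 65 were listed at 0 in a group, 46 of them in the knockout and 19 in the wild type. Values of 0 were also more frequent in the knockout over all transcripts, called or not, so this excess is not particular to the calls. Of these 65, 49 stayed under 1 FPKM in both groups and 52 lay at loci with a single transcript.

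**Figure D2:**
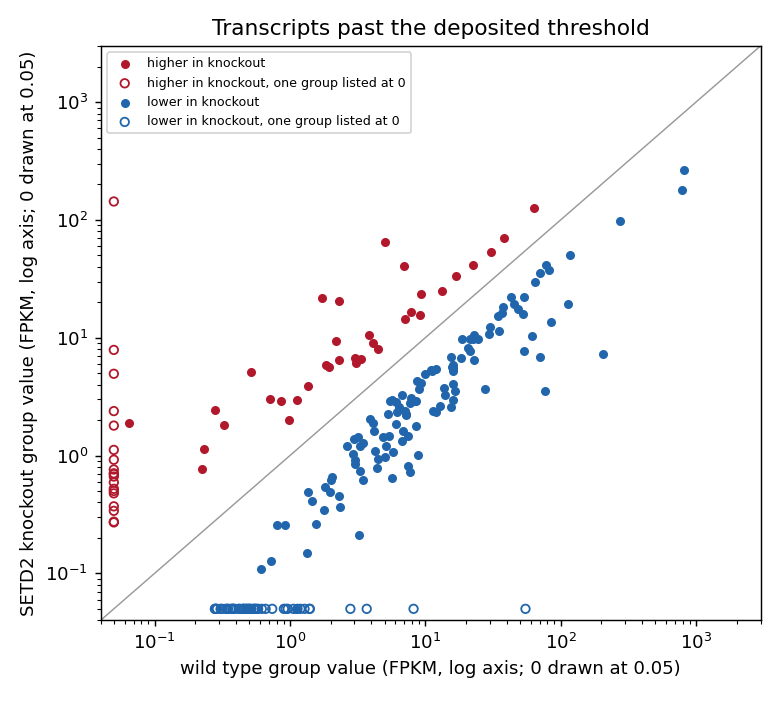
Knockout against wild type group FPKM of the 219 transcripts past the authors' threshold (both axes logarithmic, values of 0 drawn at 0.05; grey line, equal values; red, higher in the knockout; blue, lower; open circles, listed at 0 in a group). Most points lie under the line, 165 against 54 above it, and the 65 open circles lie mostly under 1 FPKM.

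The items below were ranked on the log2(FPKM + 1) scale, which gives less weight to low transcripts than the ratios printed beside them. The largest fall with values above 0 in both groups lay on chromosome 4 between positions 41222091 and 41270472, a locus of 14 transcripts. Its transcript ENST00000514764 stood at 7.26 FPKM in the knockout and 207.0 FPKM in the wild type in the authors' deposited table, a 28.5-fold fall with q = 0.0220. The authors' intervals in the tracking table, where its knockout value was 6.70 FPKM, were 0.644 to 12.7 FPKM in the knockout and 81.3 to 323 FPKM in the wild type, and did not overlap. Another transcript of the locus fell from 77.2 to 3.53 FPKM, with intervals that overlapped. Summed over all its transcripts, the locus held 17.6 FPKM in the knockout and 403.1 FPKM in the wild type.

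Of the 10 largest falls on this scale, 3 lay on chromosome X. At X:106956451-107020572 the transcript ENST00000372397 fell from 70.3 to 6.92 FPKM (10.2-fold) in the authors' deposited table, with intervals of 44.0 to 93.3 FPKM in the wild type and 3.44 to 13.6 FPKM around a knockout value of 8.53 FPKM in the tracking table. At X:112017731-112084043 a transcript fell from 53.4 to 7.67 FPKM, and its locus sum went from 177.6 to 58.8 FPKM. At X:107963179-107982133 a transcript fell from 84.9 to 13.6 FPKM, with intervals that overlapped. Both transcripts of a locus on chromosome 20, from 62119366 to 62130505, fell together, from 112.9 to 19.3 FPKM and from 61.3 to 10.3 FPKM. The intervals of the second of these transcripts overlapped. A locus of 12 transcripts on chromosome 17, from 1665253 to 1680868, had a transcript that fell from 27.8 to 3.69 FPKM, and its sum went from 76.7 to 5.16 FPKM. A pair of short loci on chromosome 7 were listed at 0 in the knockout. The first, of 113 bases at 148684228, stood at 55.0 FPKM in the wild type with an interval of 0 to 137.7 FPKM. The second, of 250 bases at 128293740, stood at 8.20 FPKM. In the tracking table the knockout values of these loci were 21.7 and 4.13 FPKM.

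Among the rises, the largest on the same scale with values above 0 in both groups was at 19:50030875-50050219. Its transcript ENST00000593483 stood at 65.0 FPKM in the knockout and 5.04 FPKM in the wild type in the authors' deposited table, a 12.9-fold rise with q = 0.0220. In the tracking table its knockout value was 79.3 FPKM with an interval of 36.9 to 121.7 FPKM, and the wild type interval was 0.454 to 9.39 FPKM. A second transcript there rose from 2.30 to 20.7 FPKM. On chromosome 13, ENST00000375856 at 110406184-110438915 rose from 1.73 to 21.9 FPKM (12.7-fold), and a transcript at 107142079-107187462 rose from 6.95 to 40.7 FPKM (5.85-fold). A transcript at 6:132269316-132398533 rose from 2.18 to 9.48 FPKM, and another at 12:130647004-130650285 rose from 0.514 to 5.10 FPKM. The remaining 4 of the 10 largest rises on this scale were short loci of 106 to 486 bases listed at 0 in the wild type. They were led by 1:174965661-174965766 at 143.5 FPKM, and the others stood at 7.89, 4.95 and 2.39 FPKM. In the tracking table their knockout values were lower, at 93.5, 5.14, 3.22 and 1.55 FPKM, each near the peak ratio of 0.652. The fixed rule named 20 transcripts at 17 loci, and for 15 of them the authors' intervals of both groups did not overlap. These 15 include the 4 short loci listed at 0 in the wild type. Their wild type interval was 0 to 0, so any knockout bound above 0 kept the intervals apart. Over all 219 calls, these 4 included, the intervals did not overlap for 93.

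At most called loci the sum over transcripts moved with the called transcript. The sum contains the called transcript, so this is in part by construction, and the other transcripts were not summed apart. Of the 128 called loci with several transcripts, the sum over transcripts changed at least 1.5-fold in the direction of the call at 115, and less than 1.2-fold or the other way at 5. In 4 bins of equal size by mean FPKM, from the lowest to the highest, 55, 26, 57 and 81 transcripts were called, and 27.3%, 26.9%, 22.8% and 23.5% of them were higher in the knockout. Of the 55 in the lowest bin, 51 were listed at 0 in a group. Over the 9506 loci of at least 5 FPKM without a called transcript, 82.4% lay within 1.5-fold, while 516 differed at least 2-fold without a call. The median log2 fold of knockout over wild type over 12424 loci of at least 1 FPKM was 0.06.

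The chromosomes of the changed loci were compared because a knockout line grown from few cells can differ from its parental culture in chromosome copies. Transcripts that fell were more frequent on chromosome X than elsewhere, 17 of 2479 tested (0.686%) against 0.178% (two-sided Fisher exact test, adjusted p = 0.000309 over 46 chromosome and direction pairs). Those that rose were more frequent on chromosome 13, 6 of 1139 (0.527%) against 0.0567% (Fisher exact test, adjusted p = 0.00186). No other pair passed. Transcripts of a locus share reads, and counted by loci the fall on chromosome X had an adjusted p = 0.0680 and the rise on chromosome 13 an adjusted p = 0.0323 (Fisher exact test). The rises on chromosome 13 started at 77454312, 100634026, 107028911, 107142079, 107820883 and 110406184, so most lay in a single region. That at 107028911 was listed at 0 in the wild type. The Fisher test counts neighbouring loci as independent, so it cannot tell a changed region from a trait of the whole chromosome.

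Folds of all expressed loci, called or not, set chromosome 3 apart. Over its 664 loci the median log2 fold was -0.22, below all of 10000 random sets of loci matched on expression, and 71.8% of its loci lay under the median of all loci. In the tracking table its median was -0.23. Chromosome X, with a median of -0.06 over 555 loci, also lay below all 10000 sets in both tables. Chromosome 19 did so with a median of -0.09 in the test table, but had a median of 0.05 and the 1.43 percentile in the tracking table. Chromosomes 4 and 5 lay above all sets, with medians of 0.18 and 0.17, and at percentiles of 99.7 and 99.9 in the tracking table. Loci are not replicates, so these percentiles describe the sequenced libraries only.

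**Figure D3:**
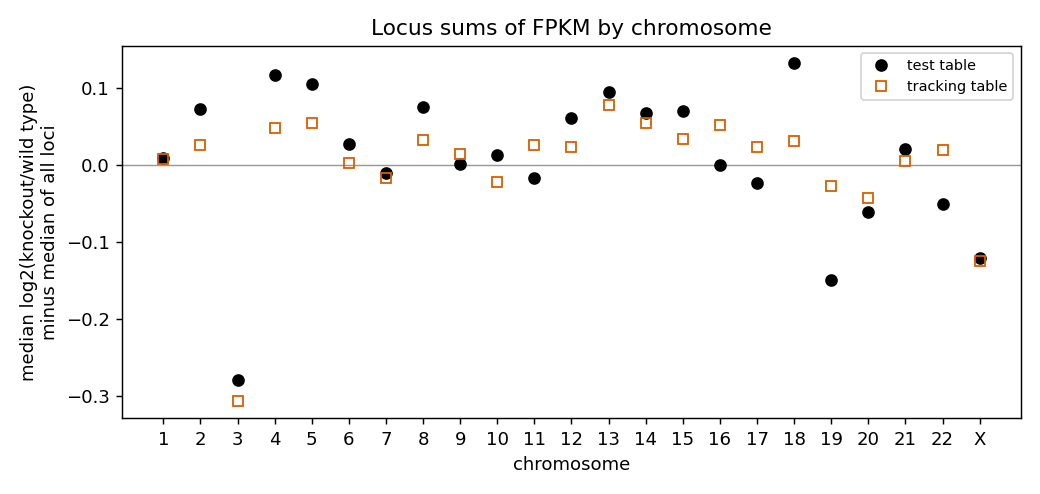
Median log2 ratio of knockout to wild type FPKM, summed per locus, for each chromosome, minus the median of all loci (filled circles, test table; open squares, tracking table). Chromosome 3 stands lowest in both tables, at -0.28 and -0.31, while chromosome 19 stands at -0.15 in the test table and at -0.03 in the tracking table.

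The lower values on chromosome 3 extended over most of its length. A scan for a single step placed it between locus starts 177919838 and 178735011. The 579 loci before the step had a median log2 fold of -0.27 and the 85 loci after it one of 0.27; none of 9999 random orders of the loci gave as large a step (permutation p = 0.0001, the smallest they can give). Before the step 77.0% of loci lay under the median of all loci. The lowest 10-Mb window was that from 120 Mb, with a median of -0.52 over 63 loci. Windows near 0 also lay before the step, with -0.05 over 23 loci from 20 Mb and 0.01 over 15 loci from 90 Mb. Chromosome 10 had a step at 27.0 Mb, with a median of -0.43 over the 77 loci before it and 0.13 over the 421 after it. On chromosome X the step fell at 100.2 Mb, with 0.08 before and -0.26 after. The steps of chromosomes 10 and X had the same permutation p = 0.0001. In the tracking table the steps of chromosomes 3 and 10 fell at 178.9 and 27.3 Mb, while that of chromosome X fell at 70.5 Mb with a median of -0.20 after it. Over the 23 chromosomes scanned, 11 had a step at an adjusted p under 0.05, and 6 had in the tracking table. The steps of chromosomes 1, 8, 9, 11 and 16 passed in the test table only. In the tracking table their adjusted permutation p were 0.292, 0.506, 0.187, 0.506 and 0.0572. Sets matched on locus density were drawn for chromosome 3 only, so a trend with density was not weighed for the other steps.

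**Figure D4:**
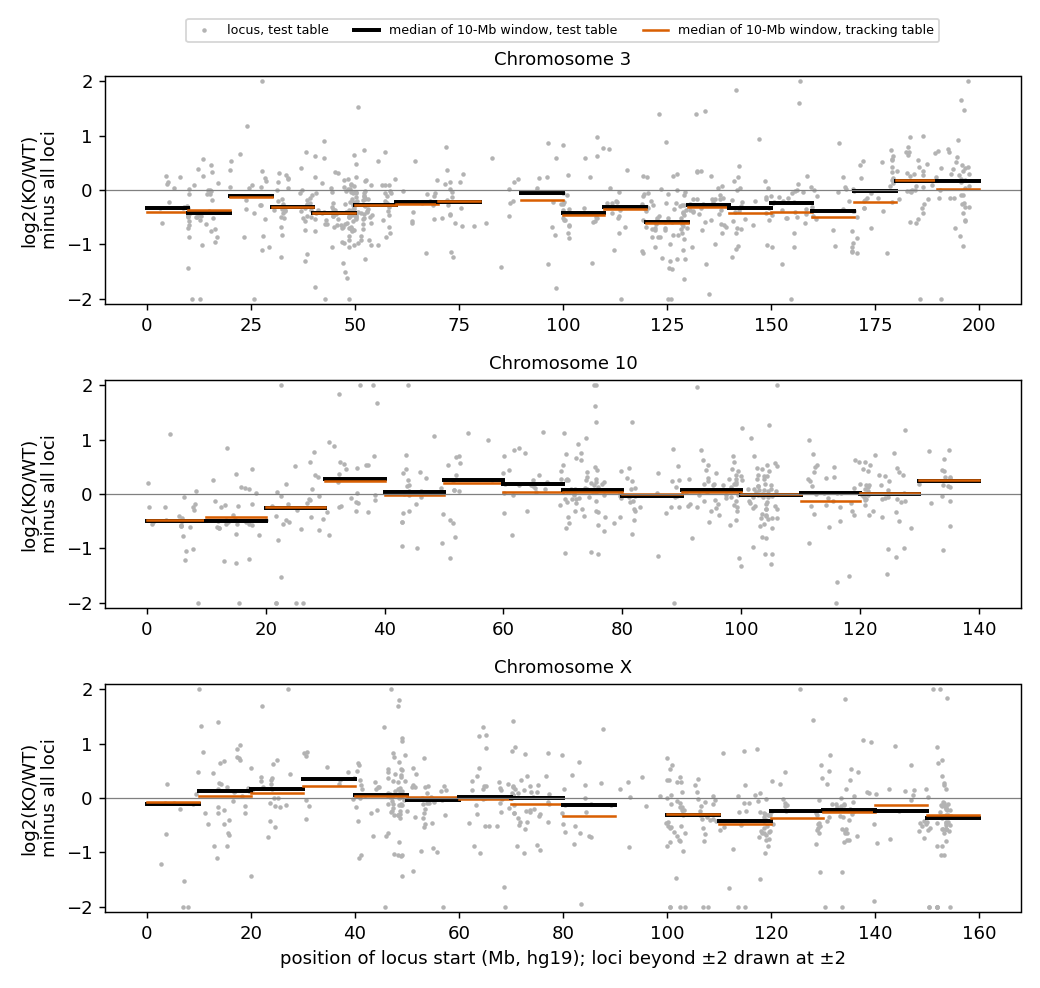
Log2 ratio of knockout to wild type FPKM along chromosomes 3, 10 and X (hg19), minus the median of all loci (grey points, loci of at least 1 FPKM; black and orange bars, medians of 10-Mb windows in the test and the tracking table). Bars lie under 0 up to about 170 Mb on chromosome 3, over the first windows of chromosome 10 and from 100 Mb on chromosome X, whose bars before 100 Mb lie on both sides of 0, at -0.13 in the test table and -0.34 in the tracking table in the window from 80 Mb.

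Gene length was compared with the fold because H3K36me3 lies along gene bodies. Across 12424 loci, which are not independent replicates, the log2 fold had a Spearman correlation of 0.0918 with locus length. In 4 bins of equal size by length, from the shortest to the longest, the median log2 fold was 0.01, 0.02, 0.10 and 0.12, and 0.998%, 1.19%, 0.869% and 0.547% of loci held a transcript that fell. Loci with a transcript that rose made up 0.322%, 0.193%, 0.225% and 0.354% of the same bins. The correlation was -0.000435 with the values of the tracking table, so no such relation was seen with those knockout values.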

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

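The tests of the table difference and of calls listed at 0 were chosen only after the results were seen; so was the share of loci used for chromosome 3, whose other tests were set before their results but after the pattern was noticed.

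In values outside the main comparison, 6718 transcripts were listed at 0 for the knockout in the test table and above 0 in the tracking table, against 194 for the wild type. A candidate explanation is that the tracking table averages 1 more knockout library than the test table: a library can then add to the mean but never take away, so with 2 of 3 libraries in the test table the ratio has a floor at 2/3 of the wild type ratio, or 0.651, and 0.011% of transcripts lay more than 2% below it while 17974 lay within 1% of it. Another scaling of the same libraries was argued against, since the 95th percentile of the ratio was 2.53 times the 5th. Another split of reads among transcripts of a locus was argued against too, since at loci with a single transcript the same ratio of percentiles was 2.18. Which libraries entered either column stays open, and no biological explanation was tested, since both columns are knockout values.

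The lower knockout level over chromosome 3 before its step was weighed as the second pattern. In 4 bins of equal size by expression level the segment lay below all loci by similar amounts, the smallest difference being -0.33. This fits fewer copies of the segment in the knockout cells as a hypothesis. The segment was chosen on these same folds, and any fall spread over its loci would give a like result, so the bins do not single out copy number. A few strongly changed genes were argued against, since 77.0% of the loci of the segment lay under the median of all loci. A trend with expression level or gene density was argued against, since the segment lay at -0.37 relative to sets matched on both. Because the end of the segment was placed on these same folds, 1000 matched copies of the chromosome had their end placed alike. Of these copies, 0 had a stretch of as many loci as low (lowest median -0.01, against -0.27). The copies were matched on level and density only and do not keep neighbouring loci together, so they cannot weigh genes of a region that change together. The effect of lacking SETD2 itself stays open and was not tested, and neither was GC content, since no genome was used here and the labels name no clones.

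The third pattern was the 65 calls with a group listed at 0. If the tables differ by a knockout library, that library can be computed from both. Among the 19 calls listed at 0 in the wild type it lay under 10% of the knockout value in 17 and above 50% in 1, which is consistent with low read support in few libraries. Another split of reads among transcripts of a locus was argued against as the whole cause, since 80.0% of the 65 calls lay at loci with a single transcript. Of the 46 calls listed at 0 in the knockout, the computed library was at 0 in 25 and above 50% of the wild type value in 14; whether the others reflect a loss of expression stays open.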

How the results depend on the processing

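Of 21 alternatives run, 12 were counted as the same as the result reported, among them counts of 154 to 217 calls against 219. The q-value of 0.01 and the minimum of 1 FPKM were run for genes and for transcripts on identical values, so each enters more than once. Chosen after seeing the data were the comparisons with the tracking table, the deposited intervals, loci against transcripts and values above 0. So were centring over chromosomes, the minimum of 5 FPKM for chromosome 3 and loci with 1 transcript. The count of 219 calls, for genes and transcripts alike, became 0 at a q-value of 0.01. The reason is that the step of the authors' p-values permits no lower q than 0.0220. Of the 85852 tested transcripts, 2049 had a deposited p-value of at most 0.05. That share is smaller than the 0.05 that evenly spread p-values would give, so no excess of small p-values was seen at that bound. At the far lower bound of 0.0001 lay the called transcripts, 0.255% of those tested. That is more than the share of 0.0001 that evenly spread p-values would give. The count of calls became 114 with a minimum of 5 FPKM and 93 where the deposited intervals had to be apart. It was 202 at 2-fold or more, 165 with a minimum of 1 FPKM, 154 with both values above 0, and 217 with the same direction in the tracking table. Adjusted over the 60188 tested transcripts of at least 1 FPKM it was 182, of which 165 were among the deposited calls. The counts of 114, 93, 202, 165, 154 and 217 come from filters on the 219 calls, so they could only be lower. The wild type values of the tracking table are nearly those of the test table, so the 217 are in part by construction. Of the calls of at least 2-fold, 21.8% were higher in the knockout, and 20.5% were after centring. The number of chromosome and direction pairs past the threshold went from 2 to 1 with loci in place of transcripts. The median log2 fold of chromosome 3 went from -0.22 to -0.28 once the median of all loci was set to 0, by construction. The correlation of fold with locus length went from 0.0918 to 0.128 with a minimum of 5 FPKM and to 0.024 over the 1784 loci with 1 transcript. It was -0.000435 in the tracking table, where no relation was left; the cause was not tested. No paired analysis was possible because the columns carry group values only, and for the same reason leaving out libraries, another pseudocount in a test and other splits of the samples were not run. Alternatives on gene symbols, SETD2, PLK1 and the gene lists were not run for want of names. Without counts, what depth limits could not be measured.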

Other observations

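Every comparison here was chosen after the data were seen. If the tracking table holds 1 more knockout library, as the floor of the ratio may mean (0.011% of transcripts lay more than 2% below it), the segments can be looked at in that library. Over 8855 loci of at least 5 FPKM in both groups, its median log2 ratio to the wild type lay at -0.44 relative to all loci before the step of chromosome 3, -0.45 before the step of chromosome 10 and -0.31 after the step of chromosome X. In the knockout values of the test table the same segments lay at -0.33, -0.47 and -0.33. Relative to the test-table knockout values, the computed library lay within 0.08 of all loci in these segments, at -0.08, -0.07 and -0.06. Over single loci, however, the computed library was no closer to the knockout than to the wild type. The median absolute deviation of its log2 ratio was 0.39 against the test-table knockout and 0.34 against the wild type. Between the test-table knockout and the wild type that deviation was 0.24. The ratios to the wild type share its values, and the segments were found with them, so they are not independent of each other. The computed library also contains the test-table knockout value by construction.

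For the 154 calls above 0 in both groups, the computed library lay on the knockout side of the wild type in 154 and nearer to the knockout value, on the log scale, in 136. Among 154 uncalled transcripts matched on fold and level it lay on the knockout side in 86 and nearer to the knockout in 56. Both comparisons share the wild type values, and whether the deposited test used that library was not tested.

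In the deposited intervals of the tracking table, 235 transcripts were higher and 547 lower in the knockout without overlap. An interval of 0 to 0 in a group is apart from any interval with a lower bound above 0. Transcripts with such an interval are included and were not counted apart. Chromosome 13 had a step at 72.0 Mb, with a median log2 fold of 0.33 over the 90 loci after it and 0.12 over the 167 before it (adjusted permutation p = 0.0225). In the tracking table its step fell at 95.7 Mb, with a median of 0.36 over the 59 loci after it (adjusted permutation p = 0.0472). Chromosome 19 had a median of -0.23 over the 143 loci from 50.2 Mb on in the test table and -0.14 over 146 loci in the tracking table.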
